A study of Oryza sativa Japonica Group with 6 samples.

How the data were processed

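Roots of 6 samples, 3 control and 3 P-deficient, were each hybridised to 1 array with Cy3-labelled RNA. Per the file headers and the submitters' processing notes, the scanner images were read with Agilent Feature Extraction 10.5.1.1. The deposited files give a linear intensity per spot: the processed signal, the mean signal and the local background signal, with flags for spots well above background, saturated or outlying. The authors also deposited a table of log2 values of the same arrays. Set against the scanner values, it equals log2 of the processed signal minus the 75th percentile over all spots, so that its scale, centring and direction are known. Its medians per array are in the same unit. Any further step is not given in the sources used here.

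The main values were log2 of the processed signal minus the 75th percentile of the probes in use. Control spots, 590 control spots of the design itself and spots with outlier flags were left out, and spots of 1 probe were averaged. This left 42418 probes, of which 9500 were not well above background on all arrays of at least 1 group and were not tested. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over tested probes and a threshold of 0.05. Each gene was represented by its tested probe with the highest mean over all 6 arrays. Of 2998 genes with several probes and at least 1 call, 47 had probes called in opposite directions. For a gene not well above background on any array of a group, the fold is a bound, "at least N-fold": the mean of the brighter group against the mean of the dim group, in which each array's value is raised to the lowest signal well above background on that array where it lies below it. Gene lists were tested with camera at a fixed correlation of 0.01, then with an estimated correlation, and with fry. Of 22 lists tested as sets, 8 passed with the fixed correlation, 0 of these with an estimated one, and 12 with fry. With an estimated correlation, camera takes its p from the 4 residual degrees of freedom and so has little power. A list that does not pass there is not shown to be unchanged. The lowest unadjusted p there was 0.0183, for iron acquisition. With slide as a random block and with a robust prior, the form of camera for precomputed statistics was used, whose p in the main setting differed from that of camera by at most 1 unit in the third digit.

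The lists, the rule for named genes, the tests of the groups and of the lists, and the alternatives named first below were fixed before the data were examined. Some tests of explanations were chosen later, as the closing section says. Named genes were the 10 largest rises and 10 largest falls with groups that do not overlap, a description, and a probe well above background on all 3 arrays of the brighter group and saturated on none, a set of genes fixed by name, and up to 4 members of each list with the lowest p. Descriptions such as hypothetical protein or no hit were taken as no description. List patterns ran on descriptions: the heat shock list includes DnaJ genes, the pathogenesis-related list includes ERF domain genes, and the ribosomal list includes a mitochondrial protein gene. Loci and descriptions are those of the array files, while gene symbols were set to loci from general knowledge before the data were examined and could not be checked against a reference here. The gene table given carries no such loci, so genome coordinates were not used here. OsD27 has no probe among those used.

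Alternatives were quantile normalization, median centring, normexp with an offset of 50, other filters on dim probes, a floor, slide as a random block, the replicate number as a block, another variance prior, the authors' deposited values, the mean of all probes of a gene, and each array left out in turn. Removing a trend on probe GC content, scaling to the spike-in RNAs and 4 other background treatments were added after seeing the data. The fit was tested on simulated data for P_deficient against control on 32902 probes. Of the simulated changes, 23 of 67 of 0.5, 51 of 67 of 1 and 63 of 66 of 2 on the log2 scale were recovered, with 7 false calls among 144. No other probes were changed, noise was drawn independently per probe, and no session effect was included. These shares therefore do not carry over to the real data, where 33.5% of tested probes were called.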

Results

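The series measured transcript levels in roots of the rice cultivar Nipponbare (Oryza sativa, Japonica group) on 1-colour Agilent oligonucleotide arrays. Seedlings grown in nutrient solution were moved either to solution without phosphate or to control solution, and roots were collected 5 days later. There were 3 control arrays and 3 P-deficient arrays. The labels number the samples of each group as replicates and do not say whether they came from separate cultures, so that p-values measure the spread between these samples, which may be technical. The 75th percentile of the signal ranged from 4889 to 5865 over the arrays. Between 73.8% and 81.9% of the spots in use were well above background on each array, and no such spot was saturated. The number of arrays limits the precision of each value. All control arrays were scanned in 1 session and all P-deficient arrays in another, 1043 days later, and no session or slide held both groups. Scan session and group therefore cannot be told apart in any value given here.

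The comparison of P-deficient with control roots asks which genes respond to the loss of phosphate supply. Levels are log2 signals relative to the 75th percentile of the array, so that higher and lower mean relative to the bulk of the probes. Gene symbols, such as OsIPS1, were set to loci from general knowledge and are not in the array files, nor are the roles given here for many of these genes. The non-coding RNA OsIPS1 (Os03g0146800) is a classical marker of phosphate starvation. Of the genes named here that were well above background on at least 1 array of each group, it had the largest difference. It went from -4.94 ± 0.19 (SD, n = 3) in control roots to 3.21 ± 0.31 (SD, n = 3) in P-deficient roots, a log2 difference of 8.15 ± 0.17 (SE; limma adjusted p = 1.315e-05). Of the measured genes, 10 of 12 for phosphate transport, 13 of 18 for phosphatases and nucleases and 10 of 20 for membrane lipids were higher in P-deficient roots, and 1 member of the phosphatase and nuclease list was lower. All 14 iron acquisition genes and 12 of 34 nitrogen genes were lower and 1 nitrogen gene was higher, while scaling to spike-in RNAs turned some of the falls, as given below for each group. None of these lists passed the set test with an estimated correlation (adjusted p from 0.402 to 0.719). That test rests on 4 residual degrees of freedom, so the lack of a pass says little. Of 32918 probes tested, 5517 were higher and 5509 lower, and 573 were at least 2-fold higher and 711 at least 2-fold lower. Counted with 1 probe per gene, 4007 of 22654 genes were higher and 3685 lower. The groups did not overlap for 51.8% of tested probes, against 10% expected by chance.

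These directions depend on the scale. The spike-in RNAs, added to the total RNA before labelling per the labels' protocols, were lower in the P-deficient arrays. The 7 that were well above background on all 6 arrays differed by -1.36 to -1.14 on the log2 scale. The amount of these spike-in RNAs per total RNA is not given in the sources used here. When the arrays were scaled to these RNAs, a choice made after seeing the data, 31882 probes were higher and 271 lower, the median log2 difference of all tested probes was 1.27, and 99.2% of the calls were higher. Of the named genes that were lower, 45 in number, 21 were still called lower, 18 were called higher and 4 lay above 0 without a call, while all 58 higher ones stayed higher. With normexp background correction the counts were 499 higher and 680 lower, and the median log2 difference was 0.198. Its background fit stood apart on P_deficient replicate 3 (SD 1613, against at most 2.06 on the other arrays). The same mean signals with no background correction gave 5688 higher and 6766 lower. Without control replicate 1, control replicate 3 or P_deficient replicate 3, the number of higher probes was 3187, 3201 and 3441.

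**Figure D1:**
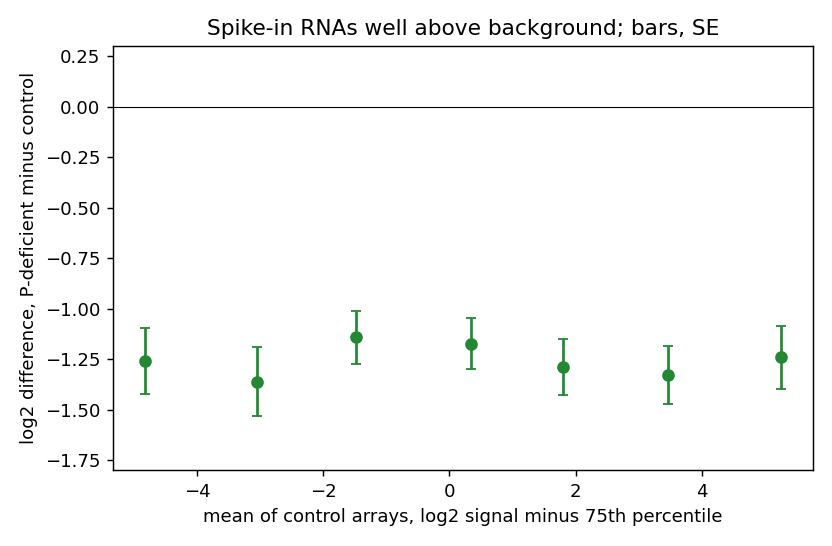
Log2 difference, P-deficient minus control (vertical axis), of the 7 spike-in RNAs well above background on all 6 arrays, against the mean log2 signal minus the 75th percentile of the control arrays (horizontal axis), with SE as bars. All 7 lie between -1.36 and -1.14.

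**Figure D2:**
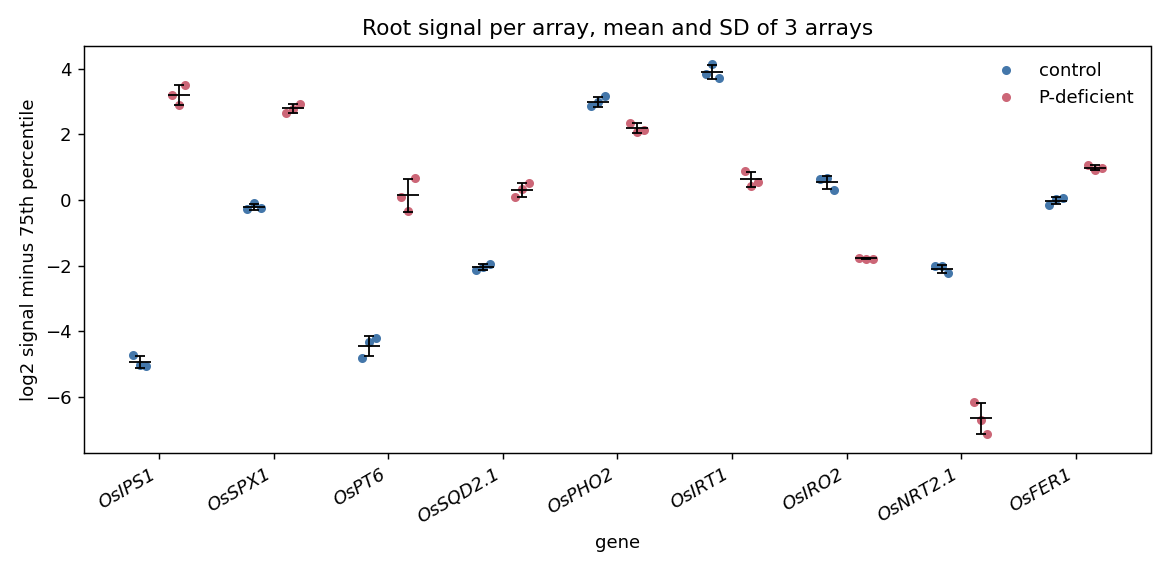
Log2 signal minus the 75th percentile of the array (vertical axis) for 9 genes, with 1 point per array, and the mean and SD of 3 arrays as bars. OsIPS1 lies at -4.94 in control and 3.21 in P-deficient roots, and OsIRT1 at 3.90 and 0.63.

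Of the 15 measured phosphate signalling genes, 7 were higher, 4 were lower and 4 did not pass the test; adjusted over the list alone the counts were also 7 and 4. The count of lower members was 2 without control replicate 1 or control replicate 3, and 0 under normexp. The higher genes besides OsIPS1 encode SPX domain proteins, which sense cellular phosphate status, among them OsSPX5 (log2 difference 5.26 ± 0.17, SE), OsSPX6 (4.02 ± 0.15), OsSPX1 (3.01 ± 0.09) and OsSPX2 (2.29 ± 0.11). OsSPX5 was well above background on 2 of the 3 control arrays, and the other probe of OsSPX1 lay at 2.42. OsPHO2, an E2 conjugase that limits phosphate uptake, had a log2 difference of -0.80 ± 0.11, and was called higher (0.45) when scaled to the spike-in RNAs, as were all 15 members. OsPHR2, the central transcription factor of the response, had a log2 difference of 0.01 ± 0.06 (adjusted p = 0.87), its other probes lay at -0.07 (adjusted p = 0.358) and 0.41 (adjusted p = 0.0602), and scaled to the spike-in RNAs the value was 1.27. The set test gave an adjusted p of 0.0103 in the higher direction, and adjusted p = 0.556 with an estimated correlation.

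Of 12 measured phosphate transport genes, 10 were higher, none was lower and 2 did not pass, with the same counts adjusted over the list alone. OsPT6 was higher, with a log2 difference of 4.60 ± 0.27 (SE) for its brightest probe and of 6.62 and 6.64 for its other 2 probes. OsPT9 was not well above background on any control array and was at least 8.52-fold higher. OsPT2 (0.99 ± 0.09 for its brightest probe, and 1.19 to 1.54 for its other 7), OsPT1 (0.46 ± 0.13, and 0.31 and 0.36 for its other 2) and OsPT8 (0.39 ± 0.10, and 0.58 for its other probe) were also higher. The brightest probe of OsPT1 did not pass without any 1 of the control arrays (0.41, 0.50 and 0.46 for replicates 1 to 3), P_deficient replicate 2 (0.46) or P_deficient replicate 3 (0.32). That of OsPT8 did not pass without control replicate 2 (0.35), control replicate 3 (0.35), P_deficient replicate 2 (0.39) or P_deficient replicate 3 (0.33). OsPHO1;2, which loads phosphate into the xylem, had a log2 difference of -0.15 ± 0.06 (adjusted p = 0.119), and of 1.11 when scaled to the spike-in RNAs. For this list the set test had adjusted p = 2.96e-05 in the higher direction, and adjusted p = 0.556 with an estimated correlation. Under normexp 5 members were higher.

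Among 18 phosphatases and nucleases, 13 were higher, 1 was lower (2 without control replicate 1) and 4 did not pass, with the same counts over the list alone. The higher ones included Os08g0280100, described as a phytase gene and here taken as OsPAP23 (log2 difference 3.75 ± 0.15, SE). Higher as well were the purple acid phosphatase genes Os10g0116800 (3.66 ± 0.13), Os01g0776600 (1.85 ± 0.10) and Os12g0637100 (1.79 ± 0.09), here taken as OsPAP3b, OsPAP10a and OsPAP10c. OsPAP23 was well above background on 2 of 3 control arrays, and the other 2 probes of OsPAP10c lay at 2.47 and 2.40. Tested as a set, these genes had adjusted p = 2.84e-05, and adjusted p = 0.556 with an estimated correlation. Of 20 membrane lipid genes, 10 were higher, 0 were lower and 10 did not pass, also adjusted over the list alone. They included OsMGD2 (6.02 ± 0.28), a galactolipid synthase gene that was well above background on 2 of 3 control arrays, the sulfolipid synthase gene OsSQD2.1 (2.36 ± 0.11) and the phosphodiesterase gene OsGDPD1 (1.56 ± 0.09). The set test gave adjusted p = 0.0103, and adjusted p = 0.556 with an estimated correlation. Under normexp 8 phosphatase and nuclease genes and 5 lipid genes were higher.

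All 14 measured iron acquisition genes were lower relative to the 75th percentile, over all probes and adjusted over the list alone. OsIRT1, the root ferrous iron transporter, fell from 3.90 ± 0.21 to 0.63 ± 0.24 (SD, n = 3 each), a log2 difference of -3.27 ± 0.15 (SE). The mugineic acid pathway genes OsDMAS1 (-2.80 ± 0.11), OsTOM1 (-2.76 ± 0.08) and OsYSL15 (-2.42 ± 0.09) and the regulator OsIRO2 (-2.33 ± 0.10) were also lower, and OsNAS1 (-0.79 ± 0.09) was lower by less and was called higher (0.47) when scaled to the spike-in RNAs. As a set the list had adjusted p = 3.35e-14 in the lower direction, and adjusted p = 0.402 with an estimated correlation. Scaled to the spike-in RNAs, 9 members were lower and 3 were higher. Of 6 iron storage genes, 3 were higher, namely OsFER1 (1.01 ± 0.08), OsFER2 (0.94 ± 0.07) and OsVIT2 (0.72 ± 0.09), and 1 was lower, the nicotianamine synthase gene OsNAS3 (-1.91 ± 0.11). Scaled to the spike-in RNAs 5 storage genes were higher and 1 was lower. Adjusted over the list alone the counts were 3 and 1.

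Of 34 nitrogen genes, 12 were lower, 1 was higher (2 without P_deficient replicate 2) and 21 did not pass, with the same counts over the list alone. The nitrate transporter gene OsNRT2.1 (Os02g0112100), described in the array files only as BCH2, had a log2 difference of -4.57 ± 0.23 (SE) and was well above background on 2 of 3 P-deficient arrays. The ammonium transporter genes OsAMT1;2 (-2.77 ± 0.21) and OsAMT1;1 (-1.24 ± 0.09) and the glutamine synthetase gene OsGS1;2 (-1.58 ± 0.14) were lower, of which OsAMT1;1 (0.017) and OsGS1;2 (-0.32) did not pass when scaled to the spike-in RNAs. The set test gave adjusted p = 0.0053, and adjusted p = 0.719 with an estimated correlation. Scaled to the spike-in RNAs, 3 members were lower and 24 higher, and under normexp 2 were lower. All 7 measured strigolactone genes passed the test, 4 higher and 3 lower, over all probes and over the list alone. The synthesis genes Os01g0700900 (3.21 ± 0.17) and Os01g0701400 (2.41 ± 0.17), which encode MAX1-type cytochromes P450, and OsD17 (1.83 ± 0.13) were higher and the receptor gene OsD14 (-0.76 ± 0.09) was lower, but was called higher (0.50), as all 7 were, when scaled to the spike-in RNAs. The set test of this list did not pass (adjusted p = 0.467).

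**Figure D3:**
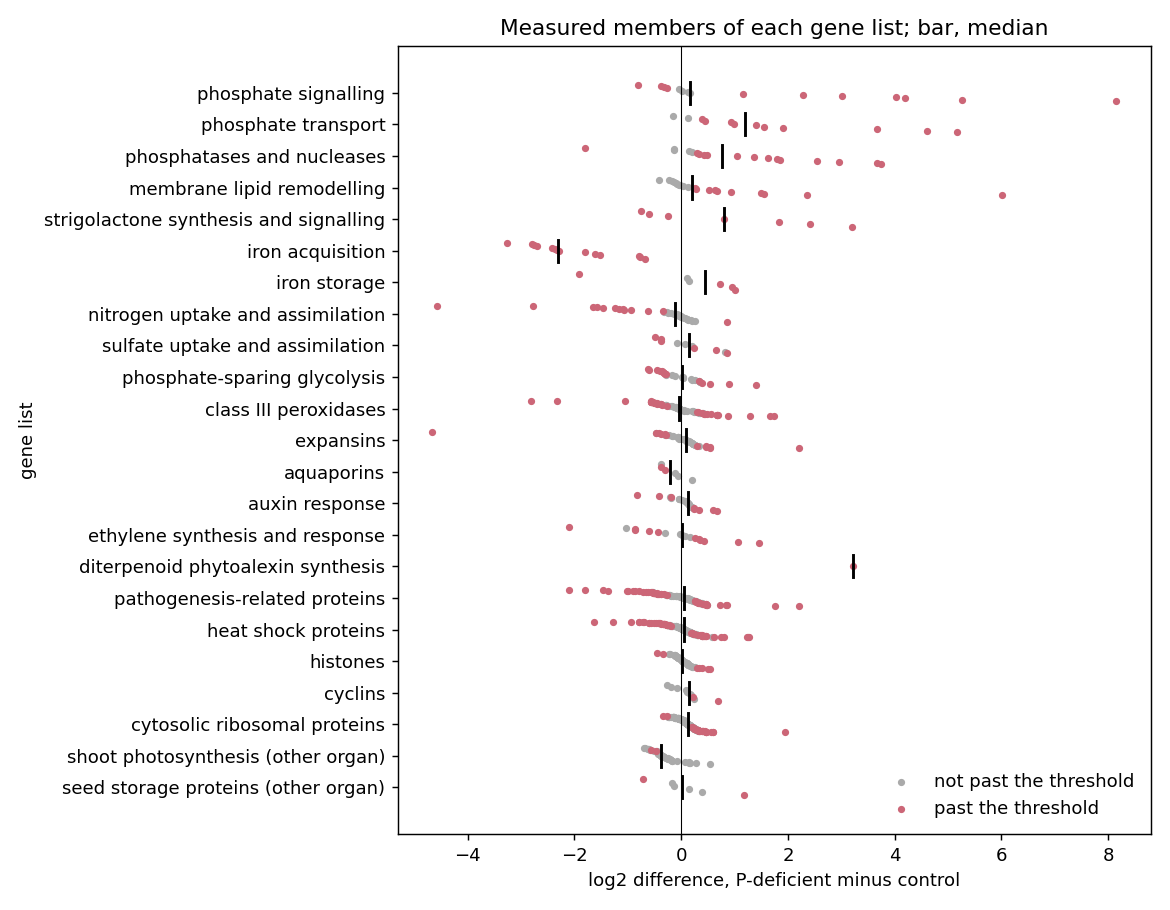
Log2 difference, P-deficient minus control (horizontal axis), of each measured member of 23 gene lists (vertical axis), with members past the adjusted p threshold of 0.05 in red, others in grey, and the median as a bar. The 14 iron acquisition genes all lie below 0 relative to the 75th percentile; scaled to the spike-in RNAs 3 of them were called higher.

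The other lists had called members in both directions or few of them, relative to the 75th percentile; scaled to the spike-in RNAs nearly all their members were called higher, such as 60 of the peroxidases, 117 of the heat shock and 157 of the ribosomal protein genes. Counts of members higher and lower were 3 and 3 of 10 for sulfate genes, 5 and 10 of 28 for phosphate-sparing glycolysis, 15 and 16 of 63 for class III peroxidases, 6 and 6 of 40 for expansins, and 0 and 2 of 6 for aquaporins. They were 5 and 3 of 25 for auxin response, 6 and 5 of 17 for ethylene, 18 and 26 of 92 for pathogenesis-related proteins, 21 and 28 of 120 for heat shock proteins, and 5 and 2 of 46 for histones. Adjusted over the list alone, these lists gave 4 and 3, 7 and 11, 17 and 19, 6 and 6, 0 and 2, 5 and 3, 6 and 6, 19 and 27, 24 and 28, and 2 and 0, in the same order. Single arrays moved several of these counts by over 1.5 times. Without control replicate 1, the higher members were 3 for glycolysis, 3 for expansins, 3 for auxin response, 9 for pathogenesis-related proteins, 11 for heat shock proteins and 2 for histones, and the lower ones 1 for sulfate genes, 5 for glycolysis, 0 for aquaporins, 18 for heat shock proteins and 1 for histones. Leaving out control replicate 2 gave 10 higher for pathogenesis-related and 12 for heat shock proteins, and 1 lower for sulfate genes and 0 for histones. Leaving out control replicate 3 gave 3 higher for glycolysis, 3 for auxin response, 9 for pathogenesis-related and 11 for heat shock proteins, and 3 lower for glycolysis, 0 for aquaporins, 14 for heat shock proteins and 1 for histones. Without P_deficient replicate 1 glycolysis had 3 higher, and without P_deficient replicate 2 aquaporins and histones had 0 lower. Without P_deficient replicate 3 there were 3 higher for auxin response, 10 for pathogenesis-related and 11 for heat shock proteins, and 5 lower for glycolysis, 0 for aquaporins, 15 for heat shock proteins and 1 for histones. The list named for cyclins caught only kinases, a kinase subunit and kinase inhibitors, with 2 higher and 0 lower of 10 (4 and 2 over the list alone; 1 higher without any 1 control array or P_deficient replicate 1, and 1 lower without P_deficient replicate 3). Cytosolic ribosomal protein genes had 25 higher and 2 lower of 157 (12 and 1 over the list alone; set test adjusted p = 0.00225, and adjusted p = 0.88 with an estimated correlation), and 55 were higher under quantile normalization and 0 under normexp. The higher ones were 9 without control replicate 1 or 3, 13 without P_deficient replicate 1 or 3 and 39 without P_deficient replicate 2, and the lower ones were 6 without P_deficient replicate 1, 1 without P_deficient replicate 2 and 0 without any other array. Set tests of lists that did not pass had adjusted p from 0.163 to 0.893. The 1 measured gene of the diterpenoid list, Os02g0278700, was at least 5.42-fold higher. Median, mean and set test differed in sign for phosphate-sparing glycolysis, expansins, ethylene and pathogenesis-related genes.

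Genes of other organs were followed as a check of the tissue. Of 42 shoot photosynthesis genes, 2 were lower and 0 higher (0 and 0 over the list alone), with a median log2 difference of -0.37, whereas all 42 were called higher when scaled to the spike-in RNAs. The count of lower members rests on single arrays: it was 10 without control replicate 2, 0 without control replicate 1 or P_deficient replicate 3, and 1 without any other array. The set test gave adjusted p = 0.0103 in the lower direction, and adjusted p = 0.88 with an estimated correlation. Of 6 seed storage protein genes, 1 was higher and 1 lower (2 and 1 over the list alone); the lower count was 4 without control replicate 1 and 0 without control replicate 2 or 3 or P_deficient replicate 2 or 3.

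Among genes with a description, the largest rises besides OsIPS1 included Os01g0700500, a cytochrome P450 gene (at least 47.9-fold), Os03g0430500, a subtilisin-like peptidase gene (at least 40.2-fold), Os05g0590300, an esterase gene (at least 14.7-fold), and Os04g0643500, an oxygenase gene (at least 10.3-fold). None of these 4 was well above background on any control array, so their place among the largest rises rests on signals that were not. The largest falls included Os12g0247700, a beta-glucosidase aggregating factor gene (at least 21.9-fold, but 37.8-fold without control replicate 1 and 13.0-fold without control replicate 3), Os02g0484200, a transferase gene (at least 15.2-fold), and Os01g0772100, a LOB domain gene (at least 15.2-fold, and 25-fold without control replicate 3), none well above background on a P-deficient array. Their place among the largest falls likewise rests on signals not well above background. Os01g0191200, an acid phosphatase gene well above background on all arrays and outside the phosphatase and nuclease list, had a log2 difference of -6.24 ± 0.31 (SE). The probe for OsIPS1, a non-coding RNA, carries the part label UTR in the array files and has the sequence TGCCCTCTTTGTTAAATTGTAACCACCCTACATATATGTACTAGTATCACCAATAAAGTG. The gene is on chromosome 3, as its locus identifier gives it. OsSPX-MFS1 and OsD10 were not well above background on enough arrays to be tested.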

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

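Signal over background limits what could be tested: 9500 probes were too dim. Scaling to the spike-in RNAs, the GC trend and 4 background treatments were chosen after seeing the data. Probe counts stayed within 1.5 times the main counts in both directions under quantile normalization, median centring, a floor, slide as a random block, a robust prior and the deposited values. Normexp gave 499 probes higher and 680 lower, 245 and 205 of them at least 2-fold. It kept 1175 of 11026 calls. The log2 difference of 1630 changed sign, with 0 called in the opposite direction. Its background fit gave P_deficient replicate 3 a mean of -1435 and an SD of 1613, against an SD of at most 2.06 on the other arrays, and the mean correlation of that array with its group went from 0.996 to 0.947. Normexp without an offset gave 499, 658, 254 and 203. The mean signal with no background correction gave 5688 probes higher and 6766 lower. With the background subtracted and a floor of 1 it gave 6398 and 6342, and the processed signal plus the offset gave 5797 and 5621. Scaling to the spike-in RNAs gave 31882, 271, 26528 and 139, kept 5784 calls and called 4528 in the opposite direction, since it moves all probes by the spike-in difference. With no dim filter, where the 9500 dim probes were tested too, 1186 probes were at least 2-fold lower and 614 at least 2-fold higher, against 711 and 573. Calls of any size were fewer, with 3914 higher and 4796 lower. Why the rise lay mostly among lower probes was not tested. Without control replicate 1, where 34132 probes were tested, 1032 were at least 2-fold lower and 519 at least 2-fold higher. Probes higher ranged from 3187 to 5178 with each array left out in turn, with 3187 without control replicate 1, 3201 without control replicate 3 and 3441 without P_deficient replicate 3. No pairing by replicate number was seen. Deviations of same-numbered arrays correlated across probes at 0.0381, -0.0843 and -0.127, while control 3 and P_deficient 2 correlated at 0.158. Such values cannot show that the samples were not paired. With the number as a block 4074 probes were higher and 4473 lower. For the values below the cause was not tested, except that fewer arrays or other probes entered the test where the setting says so.

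With quantile normalization, members higher numbered 2 (nitrogen, seed storage), 8 (histones), 55 (ribosomal). With quantile normalization, members lower numbered 0 (aquaporins), 2 (cyclins), 1 (shoot photosynthesis). With median centring, members lower numbered 1 (cyclins). With median centring, log2 differences changed sign to -0.0022 (OsPHR2). With normexp, members higher numbered 5 (phosphate transport, membrane lipid), 8 (phosphatases and nucleases), 0 (nitrogen, expansins, auxin response, diterpenoid, heat shock, histones, cyclins, ribosomal), 1 (sulfate, glycolysis, ethylene), 2 (peroxidases), 4 (pathogenesis-related). With normexp, members lower numbered 0 (phosphate signalling, phosphatases and nucleases, glycolysis, expansins, aquaporins, auxin response, histones, ribosomal, shoot photosynthesis, seed storage), 1 (strigolactone, sulfate), 2 (nitrogen, peroxidases, ethylene), 3 (pathogenesis-related, heat shock). With normexp, log2 differences changed sign to 0.28 (Os01g0286900), 0.17 (Os12g0577700), 0.82 (Os05g0329400), 0.87 (Os07g0275100), 0.23 (Os01g0938100). With normexp, set tests that now passed had adjusted p of 0.00812 (aquaporins). With normexp, set tests that changed direction had adjusted p of 0.737 (sulfate), 0.314 (expansins), 0.659 (pathogenesis-related, heat shock, ribosomal), 0.00204 (histones). With no dim filter, members higher numbered 3 (auxin response), 11 (pathogenesis-related), 1 (cyclins), 12 (ribosomal). With no dim filter, members lower numbered 2 (phosphatases and nucleases, seed storage), 0 (aquaporins, histones, shoot photosynthesis), 1 (ribosomal). With no dim filter, set tests that changed direction had adjusted p of 0.35 (seed storage). With probes well above background on all 6 arrays, members higher numbered 0 (diterpenoid). With probes well above background on all 6 arrays, members lower numbered 1 (cyclins). With probes well above background on all 6 arrays, set tests that changed direction had adjusted p of 0.968 (seed storage). With slide as a random block, members lower numbered 1 (aquaporins, histones, shoot photosynthesis). With the replicate number as a block, members higher numbered 3 (glycolysis, auxin response), 2 (histones, seed storage), 1 (cyclins), 13 (ribosomal). With the replicate number as a block, members lower numbered 0 (histones), 1 (ribosomal, shoot photosynthesis). With a trended, robust prior, members higher numbered 2 (nitrogen), 4 (cyclins), 38 (ribosomal). With a trended, robust prior, members lower numbered 1 (cyclins, shoot photosynthesis). With the authors' deposited values, members lower numbered 1 (histones). With the mean of the probes of a gene, members higher numbered 2 (seed storage). With the mean of the probes of a gene, members lower numbered 1 (aquaporins, cyclins). With the mean of the probes of a gene, log2 differences changed sign to 0.034 (Os10g0390600). With the GC trend removed, members higher numbered 2 (seed storage). With the GC trend removed, members lower numbered 1 (histones, cyclins). With spike-in scaling, members higher numbered 15 (phosphate signalling, ethylene), 20 (membrane lipid), 7 (strigolactone), 3 (iron acquisition), 5 (iron storage), 24 (nitrogen), 10 (sulfate, cyclins), 28 (glycolysis), 60 (peroxidases), 39 (expansins), 6 (aquaporins, seed storage), 25 (auxin response), 84 (pathogenesis-related), 117 (heat shock), 46 (histones), 157 (ribosomal), 42 (shoot photosynthesis). With spike-in scaling, members lower numbered 0 (phosphate signalling, strigolactone, sulfate, glycolysis, aquaporins, auxin response, heat shock, histones, ribosomal, shoot photosynthesis, seed storage), 9 (iron acquisition), 3 (nitrogen), 2 (peroxidases, pathogenesis-related), 1 (expansins, ethylene). With spike-in scaling, log2 differences changed sign to 0.45 (OsPHO2), 1.11 (OsPHO1;2), 0.47 (OsNAS1), 0.39 (Os11g0701400), 0.25 (Os07g0125000), 0.40 (Os05g0149400), 0.65 (Os10g0390600), 0.64 (Os02g0807000), 0.66 (Os03g0401300, Os10g0419300), 0.017 (OsAMT1;1), 0.21 (Os03g0235000), 0.50 (OsD14), 0.46 (Os05g0460000), 0.78 (Os03g0132200), 0.43 (Os01g0286900), 0.87 (Os09g0240500, Os04g0521100), 0.77 (Os03g0196000), 1.00 (Os12g0577700), 0.54 (Os05g0329400), 0.79 (Os07g0275100), 0.70 (Os01g0938100), 0.56 (Os01g0881600), 0.63 (Os07g0435300), 0.89 (Os02g0658100), 0.95 (Os07g0448800). With an estimated correlation, set tests that no longer passed had adjusted p of 0.556 (phosphate signalling, phosphate transport, phosphatases and nucleases, membrane lipid), 0.402 (iron acquisition), 0.719 (nitrogen), 0.88 (ribosomal, shoot photosynthesis). With fry, set tests that no longer passed had adjusted p of 0.238 (ribosomal), 0.424 (shoot photosynthesis). With fry, set tests that now passed had adjusted p of 0.00099 (strigolactone), 0.00238 (iron storage), 0.0439 (sulfate), 0.035 (auxin response), 0.0172 (ethylene), 0.0254 (cyclins). With fry, set tests that changed direction had adjusted p of 0.885 (glycolysis). With each array left out in turn, members higher ranged over 1 to 2 (nitrogen), 3 to 5 (glycolysis), 3 to 8 (expansins), 3 to 7 (auxin response), 9 to 18 (pathogenesis-related), 11 to 19 (heat shock), 2 to 5 (histones), 1 to 3 (cyclins), 9 to 39 (ribosomal). With each array left out in turn, members lower ranged over 2 to 4 (phosphate signalling), 1 to 2 (phosphatases and nucleases), 1 to 3 (sulfate), 3 to 11 (glycolysis), 0 to 2 (aquaporins), 14 to 25 (heat shock), 0 to 3 (histones), 0 to 1 (cyclins), 0 to 6 (ribosomal), 0 to 10 (shoot photosynthesis), 0 to 4 (seed storage). For OsPHR2 it ranged from -0.0051 to 0.036.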

Other observations

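The miRNA probes and gene clusters below were picked after their values were seen. The tests of quantile normalization, the scan session, iron status and the gene clusters were chosen only after the result was seen, and that of GC content after the data were seen but before its own result. Of 510 probes for miRNA loci, 115 were tested, labelled as the mature part or a flank of a locus, with up to 3 tested probes per locus. Of the probes well above background on all 6 arrays, 13 of 18 for the miR169 family, from 7 loci, were lower and 0 higher, with log2 differences of all 18 from -2.08 to 0.06. Of 23 such probes for miR166, 21, from 11 loci, were higher and 0 lower, from 0.52 to 0.88. Of 4 such probes for miR398, the 3 of the locus miR398a were lower, down to -2.36. Probes of 1 locus are not independent. Loci of 1 family may not be either: the mature probes of miR166a, miR166c and miR166n had control means of -2.95, -2.99 and -2.96. They may read the same RNA, so the number of loci is not a number of separate results. These directions are relative to the 75th percentile, and scaling to the spike-in RNAs moves the median probe to 1.27, so that smaller falls would turn. What these probes measure of the mature miRNAs in labelled total RNA is not given in the sources used here.

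Higher copper status, which is known to lower miR398 and to raise its targets, is a candidate explanation for the miR398 values. Of 4 genes described as Cu-Zn superoxide dismutases, 1 was higher, Os07g0665200 (log2 difference 0.48 ± 0.06, SE), and 0 were lower. Their median was 0.0663 and most did not pass the test. The mature probe of miR398b, another miR398 locus, did not pass either (log2 difference -0.22, limma adjusted p = 0.0798). Copper status stays open. The 3 lowest members of 2 diterpenoid gene clusters, on chromosomes 2 and 4, raised the idea that the clusters may fall as units. Of 11 members measured, 5 were lower and 1 higher, but the 5 include the 3 that raised the idea. Of the lower members, Os02g0571100, Os04g0179200 and Os04g0180400 were not well above background on any P-deficient array. Os02g0571900 was so on only 1, so the sizes of these falls rest on dim signals. The 8 members not seen before gave a set test p of 0.298, and Os02g0569000 in one cluster was higher (log2 difference 1.39 ± 0.18). The test gave no evidence that the clusters fell as units.

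For the calls in both directions, which may come from phosphate supply or from a technical difference between the sessions, quantile normalization left 11607 probes called and removal of the trend on probe GC content 11196, against 11026, which argues against a scale difference that depends on signal and against GC content as the whole cause. The spike-in RNAs differed by a median of 1.258 on the log2 scale, more than the median of 0.438 of the called probes, but all 7 shifted the same way with an SD of 0.0791. By the rule written before this result, a spike-in median that reaches that of the called probes goes with a labelling or scanning difference. That rule was met. Only after the result was seen was it brought in that a shift in 1 direction cannot by itself give calls in both directions. With that later reading, the comparison leaves a labelling or scanning difference open. Growth, harvest and scan session cannot be told apart from the treatment, since 0 sessions held both groups. The real split of the 6 arrays called 11026 probes and the highest of the other splits 0 (1 of 10 splits as large), and 10 splits are too few for a share under 0.05.

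The fall of the iron acquisition genes, with a median log2 difference of -2.31, lay below all 10000 random lists of like brightness (-0.44 to 0.29). It was larger in size than the largest difference of a spike-in RNA (1.362). That argues against a shift shared by all spike-in RNAs as its whole cause. A labelling or scanning difference that acts on some genes more than on others stays open. Random lists treat genes as unrelated, and with an estimated correlation the set test of this list did not pass (p = 0.0183, adjusted p = 0.402). Higher iron status of the P-deficient roots is a hypothesis that stays open, since the values of its test had been seen before. The 5 genes tested had a median log2 difference of 0.723. Of these, OsFER1, OsFER2 and OsVIT2 were higher, while 2 genes described only as ferritin/ribonucleotide reductase-like did not pass (0.10 and 0.15). The nicotianamine synthase gene OsNAS3 of the same list, which the test left out, had -1.91. Whether that value goes with or against higher iron status was not tested. Growth, harvest and scan session stay open for the fall of the iron acquisition genes as well.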
